A study of Homo sapiens with 6 samples.

How the data were processed

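RNA was measured in 6 samples of PATU8988, a human pancreatic cancer cell line, 3 carrying a non-targeting control hairpin and 3 carrying a hairpin against CLIC1. Per the labels' protocols, the hairpins were delivered by lentivirus and infected cells were selected with puromycin for 2 weeks, so the libraries describe stable lines and not an acute knockdown. Total RNA was extracted with a phenol-based reagent, checked for integrity and prepared with a standard Illumina protocol, per the labels' protocols. Whether the kit kept strand, selected poly(A) RNA or removed ribosomal RNA is not given in the sources used here. The sequence of either hairpin, the number of different hairpins against CLIC1 and whether the 3 samples of a group were separate infections are likewise not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

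Per the submitters' processing notes, fastp, HISAT, RSEM and edgeR were used with the genome build GRCh38. Their versions, the annotation release and any filter are not given in the sources used here. The authors deposited 1 table of length-normalized transcript levels (TPM) for 60831 genes, printed with 2 decimals. TPM divides the reads assigned to a gene by its length and scales each library to the same total, and each deposited library summed to between 999988 and 999992. TPM keeps no sequencing depth, so the depth of each library is unknown, counting error cannot be separated from other spread, and no count model could be fitted. A rise in a few abundant genes lowers the TPM of all others by construction. Columns were matched to samples by the control abbreviation and the replicate number in their names. A pair of columns held the authors' group means, which lay within 3.33e-05 TPM of the means of the 3 control and 3 knockdown columns, and was not used. The table also held 209 assembled genes without a name, of which 184 entered the tests, and 1 line of the table was empty.

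Values were transformed to log2(TPM + 1), so the pseudocount was 1 and fold changes of low genes are understated on this scale. Genes with a mean TPM of at least 1 over the 6 libraries were tested, which left 14135 genes. Knockdown was compared with control by limma 3.58.1 with a mean-variance trend (R 4.3.3), with no covariate, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. A change of at least 2-fold means an absolute log2 fold change of at least 1. All adjusted p-values of single genes come from this limma test unless another setting is named. Errors printed beside TPM values are standard deviations over n = 3 libraries, and SE is the standard error of the log2 fold change.

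Gene lists were written before the data were examined, 41 in all. They cover the CLIC family and other chloride channels, metabolism, redox genes, matrix and signalling genes, epithelial and pancreatic cancer subtype markers, proliferation and stress, innate responses, library composition, and markers of other cell types. Of 1032 list members written, 1026 matched a gene of the table. Lists with at least 5 tested members, 36 in all, were tested with camera from limma at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the 36 lists. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. KEGG pathways and GO terms came from the annotation columns of the deposited table, and terms with 10 to 300 tested members were tested in the same way.

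Named genes followed a rule fixed before the data were examined. It takes CLIC1 to CLIC6; the 12 largest rises and 12 largest falls among called genes with a gene symbol whose groups do not overlap; up to 2 rises and 2 falls per list, or the member with the smallest p; 9 genes of glycolysis, Wnt and YAP signalling and MYC whatever their p; up to 3 members per annotated pathway; and the 5 largest changes in TPM each way among called genes. Names shared by several gene identifiers were not treated as symbols. Genes named outside the rule are marked as chosen after their values were seen.

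Coordinates, gene types, GC content and 3′ UTR sequences came from GENCODE release 29 on GRCh38. Of the tested genes, 98.2% had an identifier in that release. The test was run on simulated data first, with noise of the size seen in these libraries over 14135 genes in a CLIC1 knockdown against control layout. It recovered 22%, 36%, 80% and 90% of 50 genes each changed by 0.3, 0.5, 1 and 2 on the log2 scale, and 6 of its 120 calls were false. Of 40 simulated unchanged sets 0 were called, and 5 of 5 sets of 25 genes shifted by 0.3 were called. Noise was drawn independently for each gene and the sets were random. The simulation therefore cannot show how often camera falsely calls lists of correlated genes.

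Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 TPM, 4 other scalings (median ratio, trimmed mean of M values, quantile normalization, and removal of mitochondrially encoded and ribosomal protein genes), limma without the trend, library weights, a replicate block and leaving out each library. Genes listed at 0 in any library left out, smooth per-library trends in GC content, length and level removed, and genes with TGCTGA in the 3′ UTR left out were alternatives chosen after seeing the data. The 3′ UTR scan used protein-coding genes with a mean TPM of at least 5 and a 3′ UTR of at least 50 bases, 9238 genes without CLIC1. Log2 fold changes were first regressed on UTR length and GC content with their squares, and a rank-sum z was computed for each of 14917 sequences of 7 bases present in at least 100 genes (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). That scan recovered a sequence whose genes had been shifted in simulated noise.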

Results

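Bulk RNA sequencing compared PATU8988 cells carrying a hairpin against CLIC1, which encodes a chloride intracellular channel protein found both in the cytosol and in membranes, with the same cells carrying a non-targeting hairpin. There were 3 libraries in each group. The title of the series links CLIC1 to matrix stiffness and to the Warburg effect, the use of glycolysis in the presence of oxygen, so genes of glycolysis, extracellular matrix and mechanical signalling were among the groups examined. Values were TPM as deposited, and the depth of the libraries is unknown. A mean of 14051 ± 42.1 genes (SD, n = 3) reached 1 TPM in control and 14132 ± 179 in knockdown. Mitochondrially encoded genes took 17.1% ± 0.189 of the total in control and 17.3% ± 0.448 in knockdown, a difference smaller than the spread between libraries (exact permutation test, two-sided, p = 0.6).

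CLIC1 itself was lower in all 3 knockdown libraries. Its level was 306.8 ± 8.52 TPM (SD, n = 3) in control and 211 ± 7.57 TPM in knockdown, 68.8% of control, with a log2 fold change of −0.54 (SE 0.0407, adjusted p = 0.00345). The control libraries lay at 313, 311 and 297 TPM and the knockdown libraries at 219, 210 and 204 TPM. CLIC1 (ENSG00000213719) lies on the minus strand of chromosome 6, 31730581 to 31739763 in GRCh38. An exact permutation test of this gene alone gave p = 0.1, the smallest that 3 against 3 libraries allow. The call was lost in limma without the mean-variance trend, with an adjusted p of 0.0730 at the same fold change, and held in the 19 other settings (adjusted p from 0.000310 to 0.0730 over all 20). CLIC3 was at 8.01 ± 1.62 TPM in control and 12.5 ± 3.08 TPM in knockdown without passing the test (adjusted p = 0.219). CLIC4 and CLIC5 did not pass either, with log2 fold changes of −0.11 (SE 0.0799) and 0.14 (SE 0.132), and CLIC2 and CLIC6 were under the level filter. Adjusted over the list alone, CLIC1 was lower and CLIC3 higher.

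**Figure D1:**
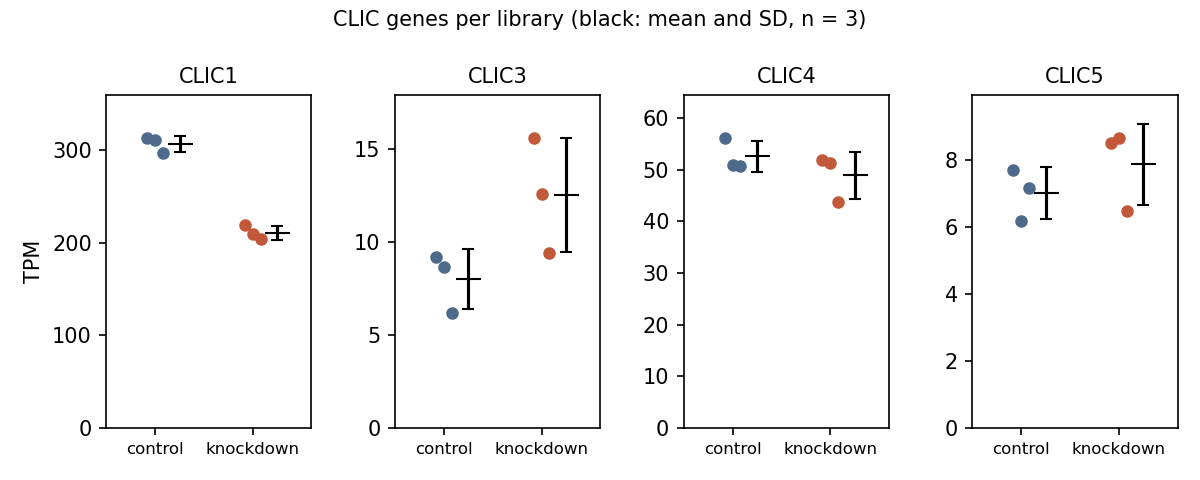
TPM of the 4 CLIC genes above the level filter in each library (vertical axis, from 0, a separate scale per gene), for control and knockdown, with the mean and SD of 3 libraries in black. The CLIC1 values of the knockdown libraries, 204 to 219 TPM, lie below those of the control libraries, 297 to 313 TPM.

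Most changes were small. Of 14135 genes tested, 246 changed, 136 higher and 110 lower in knockdown, and 19 of them changed at least 2-fold, 10 up and 9 down. The median absolute log2 fold change of the 246 genes was 0.43, and 227 of them were protein-coding. Their control and knockdown values did not overlap in any of the 246, while 22.3% of all tested genes did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 2207 genes, 15.6% of those tested. limma without the trend called 0 genes, with 2040 at an unadjusted p under 0.05. Without control replicate 1, 2 or 3 the counts were 35, 34 and 36, and without knockdown replicate 1 or 2 they were 137 and 37. Of 89 named genes, between 36 and 74 kept their side of the threshold when 1 library was left out. That count includes genes that had not been called with all libraries. Of the 65 called genes, between 14 and 53 lost the call, and 0 changed direction. HIF1A, which was not called, did change sign without knockdown replicate 3.

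The largest rises included genes of mucins, a trefoil peptide and the cornified envelope. SPRR3, a cornified envelope protein, went from 0.707 ± 0.326 to 4.15 ± 1.37 TPM (log2 fold change 1.57, SE 0.244, adjusted p = 0.0287), and CD24, a surface glycoprotein with near-identical copies elsewhere in the genome, from 3.31 ± 0.199 to 12.1 ± 3.44 TPM (1.57, SE 0.197, adjusted p = 0.0172). The gel-forming mucins MUC5AC and MUC6 both rose by 1.32 on the log2 scale, the trefoil peptide TFF1 rose from 28.1 ± 2.96 to 74.7 ± 20.6 TPM and SPINK4, a protease inhibitor of goblet cells, from 7.63 ± 1.2 to 23.2 ± 3.47 TPM. C6orf15, the decoy receptor IL1R2, the cystatin CST7, TRAPPC5, NDUFAF8 and the calcium-binding protein S100A4 completed the 12 largest rises among genes with a symbol, with log2 fold changes of 1.34, 1.25, 1.02, 0.99, 0.94 and 0.94. SPRR3 and C6orf15 were below 1 TPM in control.

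Enzymes and regulators of lipid synthesis stood among the largest falls. HMGCS1, which makes HMG-CoA for the mevalonate pathway, fell from 69.7 ± 4.42 to 33.8 ± 4.98 TPM (log2 fold change −1.03, SE 0.109, adjusted p = 0.0114). SCD, the stearoyl-CoA desaturase, fell from 139 ± 6.26 to 72.6 ± 12.1 TPM, and INSIG1, a sterol sensor partner, from 59.3 ± 2.59 to 33.1 ± 3.28 TPM. The imprinted gene MEST fell from 64.6 ± 3.46 to 29.7 ± 2.41 TPM (−1.09, SE 0.0746, adjusted p = 0.00329), and the glycolytic aldolase ALDOC from 21 ± 1.39 to 11.2 ± 1.89 TPM. ATP6V0E2, NRN1, CCDC28A, LYRM7 and BBIP1 fell by 0.90, 0.88, 0.87, 0.78 and 0.73 on the log2 scale. SAPCD1-AS1, an antisense gene on chromosome 6 (31764310 to 31765588), was at 4.05, 2.09 and 2.45 TPM in control and at 0.36 TPM in 1 knockdown library, and was listed at 0 in the others. It overlaps SAPCD1, so its reads could be mixed with those of that gene where strand was not used. A scan chosen after the data were seen found the 7 bases GTGCTGA in the 3′ UTR of 43 of the 94 lower genes that could be searched, 4 of the 127 higher ones and 10.9% of the uncalled ones. MEST, HMGCS1, SCD, ATP6V0E2, CCDC28A, LYRM7 and BBIP1 carry it, while INSIG1, ALDOC and NRN1 do not, though NRN1 carries the overlapping TGCTGAA.

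**Figure D2:**
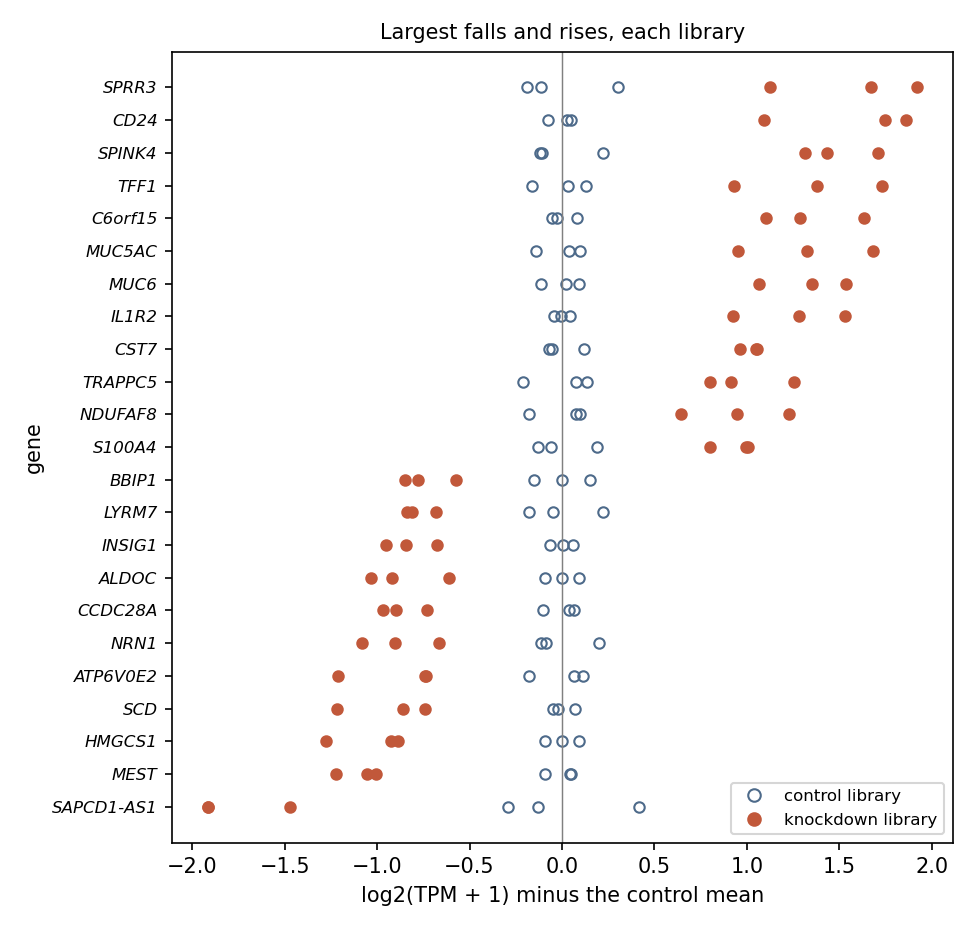
Of the largest falls and rises among genes with a symbol that passed the test, 11 falls and 12 rises, 1 line per gene, with log2(TPM + 1) of each library minus the mean of the 3 control libraries on the horizontal axis. Open points are control and filled points knockdown libraries. Only genes whose groups do not overlap were taken, so the lack of overlap here is no separate result. For SAPCD1-AS1, 2 knockdown libraries are listed at 0 and share 1 point.

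By absolute level, among genes that passed the test, the largest rises were in KRT8 (4297 ± 52.0 to 5040 ± 143 TPM) and KRT18 (4142 ± 94.3 to 4859 ± 131 TPM), the keratin pair of simple epithelia, and in S100A6, TMSB10 and CALR, which rose by 0.53, 0.16 and 0.39 on the log2 scale. RPSA (2664 ± 37.3 to 2185 ± 27.9 TPM), RPL23 (1644 ± 8.87 to 1184 ± 9.30 TPM), the metallothionein MT2A, the ATP synthase subunit ATP5MF and RPL39P3, a ribosomal protein pseudogene, had the largest falls. Genes with near-identical copies, among them the ribosomal protein and keratin genes, are uncertain where reads were split between copies, and the RPL39P3 change reversed once GC, length and level trends were removed (log2 fold change 0.08, adjusted p = 0.617).

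Of the 36 lists tested, 20 passed camera, 12 higher and 8 lower in knockdown. With an estimated correlation 0 lists passed after adjustment, and 4 had an unadjusted p under 0.05. By fry, 7 passed. These were cholesterol synthesis, G2/M, unfolded protein response, antigen presentation and histones, and pentose phosphate and NADPH oxidases, which did not pass camera. The glycolysis, epithelial, extracellular matrix and both subtype lists did not pass fry (fry adjusted p from 0.0585 to 0.201). A split of the 6 libraries other than the real one gave a smaller camera p for the glycolysis, immediate early, integrin and ribosomal protein lists, with p as small in 2, 2, 5 and 5 of 10 splits. The median and the test differed in sign for interferon-stimulated, NF-kB and apoptosis genes, and the mean and the test for NADPH oxidases and apoptosis genes.

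Cholesterol synthesis genes were lower as a list. Of its 24 tested genes 10 fell and 14 did not pass (20 lower adjusted over the list alone), 22 had negative log2 fold changes, and the median was −0.35 (camera adjusted p = 4.41e-18, and adjusted p = 0.145 with an estimated correlation). HMGCS1 and INSIG1 had the largest falls in the list. The squalene-forming and squalene-oxidizing enzymes FDFT1 (231 ± 1.47 to 165 ± 4.91 TPM, −0.48, SE 0.0365, adjusted p = 0.00345) and SQLE (50.7 ± 3.05 to 32.8 ± 2.45 TPM) fell too. So did the sterol oxidase MSMO1 (53.6 ± 3.78 to 35.02 ± 2.09 TPM). The KEGG pathway of steroid biosynthesis had 5 of 19 genes lower (adjusted p = 2.63e-05, and adjusted p = 0.998 with an estimated correlation). In fatty acid synthesis, SCD and FASN (261 ± 8.72 to 201 ± 9.58 TPM) fell and 13 of 15 genes did not pass (5 lower and 1 higher adjusted over the list alone; median −0.15, adjusted p = 0.00713, and adjusted p = 0.392 with an estimated correlation). The fatty acid median was −0.09 without knockdown replicate 3 (adjusted p = 0.00886). Once genes with TGCTGA in the 3′ UTR, and those with no searched 3′ UTR, were left out, it was −0.18 and the list no longer passed (adjusted p = 0.0609).

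Glycolysis genes were shifted slightly down as a list, and most of its enzymes did not pass the test. Of 23 genes, ALDOC and PFKFB4, a regulator of phosphofructokinase (19.2 ± 1.26 to 12.8 ± 1.46 TPM), fell and 21 did not pass (8 lower adjusted over the list alone). The median was −0.12 and 19 of the 23 values were negative (adjusted p = 1.36e-04, and adjusted p = 0.550 with an estimated correlation). Without knockdown replicate 3 the median was −0.08 (adjusted p = 0.00502). The KEGG pathway of glycolysis and gluconeogenesis did not pass, with 1 of 47 genes higher and 1 lower (median −0.08, adjusted p = 0.244). Of the GO terms, glycolytic process passed as lower, with 1 of 26 genes lower (median −0.12, camera adjusted p = 0.0200). Canonical glycolysis did not pass (1 of 24 lower, median −0.09, adjusted p = 0.0947). Neither term passed with an estimated correlation (adjusted p = 0.9998 for each). LDHA was at 1315 ± 43.9 and 1204 ± 98.1 TPM, and PKM at 2112 ± 37.4 and 2189 ± 145 TPM. The glucose transporter SLC2A1 was at 826 ± 25.7 and 943 ± 102 TPM, and HK2, whose 3′ UTR carries GTGCTGA, at 40.7 ± 2.2 and 32.9 ± 7.28 TPM. None of these 4 genes passed (adjusted p from 0.291 to 0.663). Without knockdown replicate 3, however, SLC2A1 passed as higher (log2 fold change 0.28 against 0.19 with all libraries, adjusted p = 0.0264), while HK2 moved from −0.32 to −0.15, LDHA from −0.13 to −0.06 and PKM from 0.05 to 0.10. Without knockdown replicate 1 PKM was at 0.00. HIF1A was at 42.4 ± 1.34 and 41.9 ± 3.11 TPM (log2 fold change −0.02, adjusted p = 0.922, and 0.03 without knockdown replicate 3). Hypoxia genes outside glycolysis had 0 of 27 past the threshold (0 adjusted over the list alone; median −0.12, adjusted p = 0.0680, and FAM162A at −0.20 with an adjusted p of 0.129). The direction of that list depended on knockdown replicate 3, without which its median was 0.04 (adjusted p = 0.954). It was −0.06 without control replicate 1 (adjusted p = 0.246). It passed without control replicate 2 (median −0.16, adjusted p = 0.0277), knockdown replicate 1 (−0.20, 0.0156) or knockdown replicate 2 (−0.20, 0.0131), after trimmed-mean rescaling (−0.11, 0.0495) and with replicate number as a term (−0.12, 0.0271).

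Respiratory genes did not pass as groups. Nuclear subunits of oxidative phosphorylation had 1 of 66 genes lower, ATP5MF (3 higher and 2 lower adjusted over the list alone; median 0.01, adjusted p = 0.626). The TCA cycle list had 0 of 23 (0 adjusted over the list alone; IDH3A, 32.4 ± 2.46 and 39.8 ± 2.62 TPM, adjusted p = 0.127; list adjusted p = 0.353). Mitochondrially encoded genes had 0 of 13 (1 higher and 1 lower adjusted over the list alone; MT-CYB, log2 fold change 0.38, adjusted p = 0.0603; list adjusted p = 0.714, and 0.0309 at a median of 0.02 with GC, length and level trends removed). MT-CYB passed as higher in 6 of 18 other settings, among them without knockdown replicate 1 (0.46, adjusted p = 0.0224). The pentose phosphate list did not pass (adjusted p = 0.129), though PGD fell from 177 ± 2.47 to 136 ± 6.06 TPM (1 lower adjusted over the list alone). It passed without knockdown replicate 3 (median −0.05, adjusted p = 0.0460) and with GC, length and level trends removed (−0.07, 0.0257). Among serine, one-carbon and amino acid stress genes, MTHFD2 fell from 103 ± 5.15 to 73.6 ± 1.9 TPM while the amino acid transporter subunit SLC3A2 rose from 281 ± 12.4 to 387 ± 8.78 TPM, and 21 of 23 genes did not pass (5 lower and 3 higher adjusted over the list alone). That list was lower on balance (median −0.17, adjusted p = 0.00533, and adjusted p = 0.416 with an estimated correlation), a call lost once genes with TGCTGA in the 3′ UTR, and those with no searched 3′ UTR, were left out, at a median of −0.16 (adjusted p = 0.149). CYBA, the p22phox subunit of NADPH oxidases, rose from 344 ± 6.04 to 427 ± 15.2 TPM, in a list of 5 genes that did not pass (2 higher adjusted over the list alone; adjusted p = 0.127). Antioxidant genes had 0 of 28 past the threshold (2 higher and 1 lower adjusted over the list alone; list adjusted p = 0.390), with HMOX1 at 24.6 ± 1.72 and 18.7 ± 1.64 TPM (adjusted p = 0.0864, and 0.0347 with GC, length and level trends removed).

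Proliferation lists were lower by small amounts. All 26 G2/M and mitosis genes had negative log2 fold changes, with a median of −0.18 (adjusted p = 5.33e-12; adjusted p = 0.0674 with an estimated correlation). CENPF, a kinetochore protein (105 ± 9.29 to 81.2 ± 2.20 TPM, adjusted p = 0.0490), alone fell over all genes, against 16 adjusted over the list alone. In the S phase list, TYMS, the thymidylate synthase, fell from 500 ± 6.98 to 433 ± 7.97 TPM, and 29 of 30 genes did not pass (1 lower adjusted over the list alone; median −0.08, adjusted p = 4.48e-04, and adjusted p = 0.392 with an estimated correlation). The KEGG cell cycle pathway was lower as a set (adjusted p = 0.00830, and adjusted p = 0.998 with an estimated correlation). CCND2, whose 3′ UTR carries GTGCTGA, fell from 35.5 ± 0.822 to 26.0 ± 1.03 TPM, and SFN, a 14-3-3 protein, rose from 296 ± 9.38 to 366 ± 17.2 TPM. p53 target genes had 21 of 22 positive values and 1 gene past the threshold, GDF15, a stress cytokine (492 ± 15.1 to 627 ± 49.5 TPM), with 2 adjusted over the list alone (median 0.09, adjusted p = 2.76e-04, and adjusted p = 0.392 with an estimated correlation). Without control replicate 3 that median was 0.14 (adjusted p = 1.53e-05). MYC was at 124 ± 1.33 and 109 ± 4.82 TPM (adjusted p = 0.108, and 0.0248 with GC, length and level trends removed), and the list of MYC targets and ribosome biogenesis did not pass (1 higher adjusted over the list alone; adjusted p = 0.484). NOLC1, a nucleolar protein, rose from 89.7 ± 3.17 to 119 ± 5.63 TPM. Apoptosis regulators did not pass as a list (1 higher adjusted over the list alone; adjusted p = 0.768), with BCL2L1 rising from 99.1 ± 3.09 to 128 ± 7.48 TPM.

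Genes of the endoplasmic reticulum stress response were higher as a list. Of 20 unfolded protein response genes 6 rose and 14 did not pass (12 higher adjusted over the list alone), with a median of 0.19 (adjusted p = 2.56e-10, and adjusted p = 0.280 with an estimated correlation). The calcium-binding chaperone CALR rose from 797 ± 12.8 to 1046 ± 4.99 TPM and CRELD2 from 51.7 ± 3.72 to 77.7 ± 2.91 TPM. Within the KEGG pathway of protein processing in the endoplasmic reticulum, 10 of 160 genes rose (adjusted p = 0.00830, and adjusted p = 0.998 with an estimated correlation), including the disulfide isomerases P4HB (457 ± 4.34 to 583 ± 17.5 TPM) and PDIA4 (195 ± 2.16 to 241 ± 7.92 TPM). Heat shock genes were lower on balance with 0 of 12 past the threshold (0 adjusted over the list alone; median −0.07, adjusted p = 0.0181, and adjusted p = 0.506 with an estimated correlation), with DNAJB1 at −0.16 (adjusted p = 0.112), and the call was lost without knockdown replicate 2 (median −0.06, adjusted p = 0.0752) and without the variance trend (−0.07, 0.0952).

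Epithelial genes had 5 of 24 members higher and 19 not past the threshold (10 higher and 1 lower adjusted over the list alone; median 0.12, adjusted p = 2.63e-05, and adjusted p = 0.392 with an estimated correlation). KRT19 rose from 673 ± 33.7 to 902 ± 64.0 TPM and the adhesion molecule EPCAM from 354 ± 2.73 to 446 ± 26.5 TPM. The marker lists of both expression subtypes of pancreatic cancer were higher as lists, though 20 of their 25 genes did not pass. The classical list, of secretory and gastrointestinal genes, had 3 of 12 genes higher, with SPINK4 and TFF1 first (5 adjusted over the list alone; median 0.39, adjusted p = 3.36e-04, and adjusted p = 0.392 with an estimated correlation). Without knockdown replicate 2 its median was 0.14 (adjusted p = 0.00755). The basal list, of squamous and keratinocyte genes, had 2 of 13 higher, SPRR3 and the cystatin CST6 (22.6 ± 1.3 to 36.4 ± 6.23 TPM), with 7 adjusted over the list alone (median 0.54, adjusted p = 2.43e-06, and adjusted p = 0.392 with an estimated correlation). Its median was 0.21 without knockdown replicate 1 (adjusted p = 9.79e-04) and 0.30 without knockdown replicate 2 (1.12e-04). Of 7 mesenchymal genes only S100A4 rose (43.5 ± 5.31 to 83.9 ± 6.62 TPM; 1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.721).

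**Figure D3:**
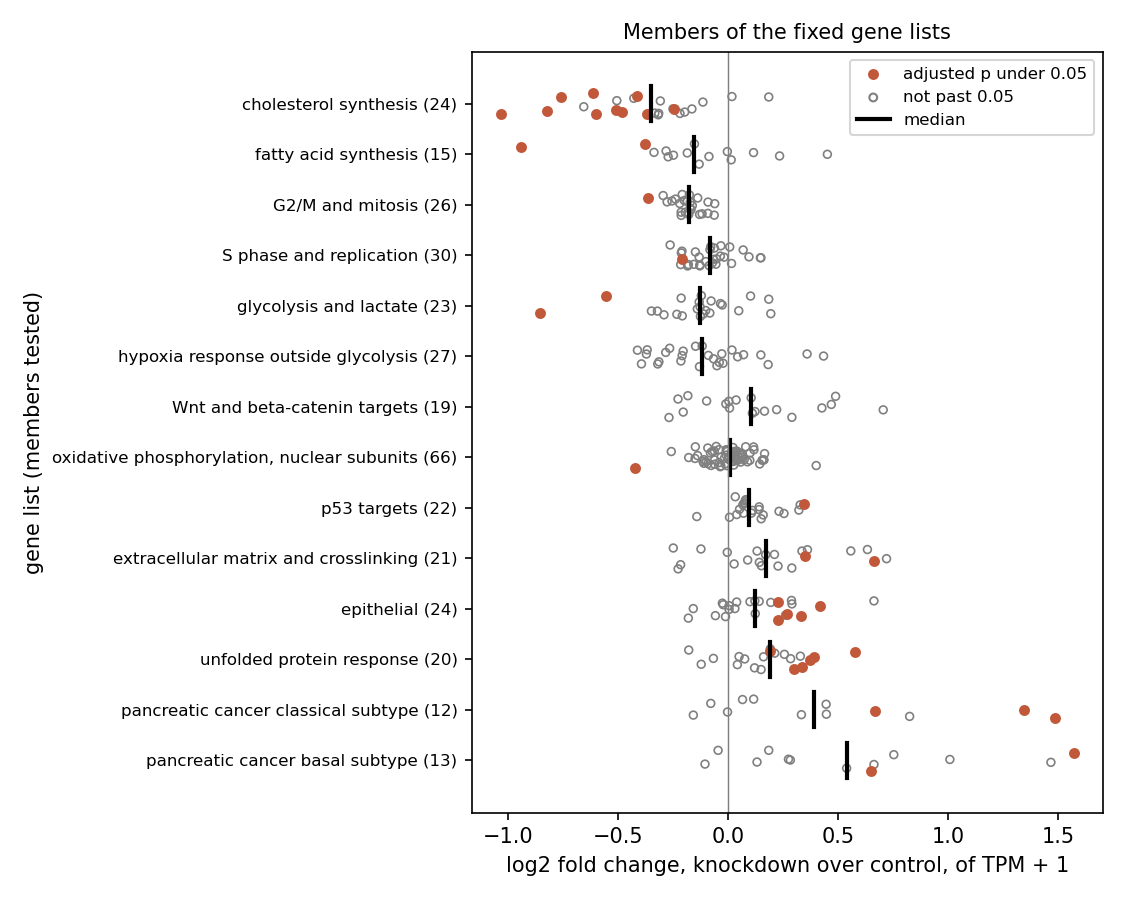
Log2 fold changes, knockdown over control, of the members of 14 gene lists fixed beforehand (vertical axis, tested members in brackets), with genes past an adjusted p of 0.05 filled and list medians as black bars. Cholesterol synthesis has the lowest median, −0.35, and the basal subtype list the highest, 0.54, which was 0.21 without knockdown replicate 1.

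Matrix and mechanical signalling lists held few genes past the threshold. Of 21 extracellular matrix and crosslinking genes, LAMB3, a chain of laminin-332 (53.1 ± 0.680 to 85.5 ± 12.7 TPM), and the lysyl hydroxylase PLOD3 (74.1 ± 3.41 to 94.7 ± 4.22 TPM) rose and 19 did not pass (7 higher and 2 lower adjusted over the list alone; median 0.17, adjusted p = 4.48e-04, and adjusted p = 0.392 with an estimated correlation). Matrix proteases and their inhibitors were higher as a list (1 of 13, TIMP1, 244 ± 3.71 to 294 ± 7.9 TPM; 5 higher and 2 lower adjusted over the list alone; median 0.25, adjusted p = 0.0151, and adjusted p = 0.439 with an estimated correlation), a call lost with a filter at 5 TPM (median 0.17, adjusted p = 0.101). YAP and TAZ target genes had 2 of 16 higher, NT5E, the ectonucleotidase CD73 (80.8 ± 7.44 to 145 ± 23.8 TPM), and tissue factor, F3 (23.3 ± 1.06 to 29.3 ± 0.134 TPM), with 3 adjusted over the list alone (median 0.09, adjusted p = 0.0205, and adjusted p = 0.392 with an estimated correlation). The YAP and TAZ call was lost without knockdown replicate 1 (median 0.07, adjusted p = 0.0584). It was also lost once genes with TGCTGA in the 3′ UTR, and those with no searched 3′ UTR, were left out, although the median was then 0.16 (adjusted p = 0.0633). Without knockdown replicate 3 the median was 0.16 and the list passed (adjusted p = 0.00633). YAP1 was at 54.6 ± 2.97 and 47.4 ± 8.31 TPM (adjusted p = 0.461). Integrin and focal adhesion genes had 1 of 29 higher, ITGA3 (71.9 ± 2.03 to 103 ± 12.97 TPM), with 3 adjusted over the list alone (median 0.04, adjusted p = 0.0271, and adjusted p = 0.711 with an estimated correlation). That call was lost without control replicate 1 (median 0.03, adjusted p = 0.0730), without knockdown replicate 1 (−0.01, 0.403), after quantile normalization (0.04, 0.0513), without the variance trend (0.04, 0.0592) and with GC, length and level trends removed (0.03, 0.105). It held without control replicate 3 (median 0.03, adjusted p = 0.0299) and without knockdown replicate 3 (0.10, 5.95e-04).

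Among TGF-beta targets, ID1 (484 ± 15.1 to 636 ± 23.8 TPM) and ID3 (146 ± 6.81 to 183 ± 8.26 TPM) rose while ID2, whose 3′ UTR carries GTGCTGA, fell (351 ± 1.77 to 246 ± 4.28 TPM), and 13 of 16 genes did not pass (5 higher and 2 lower adjusted over the list alone). That list did not pass (adjusted p = 0.0680). It did without knockdown replicate 3 (median 0.16, adjusted p = 0.0421), with library weights (0.14, 0.0422) and once genes with TGCTGA in the 3′ UTR, and those with no searched 3′ UTR, were left out (0.23, 4.09e-05). Wnt and beta-catenin targets had 0 of 19 past the threshold (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.111, and 0.0234 with no level filter), with EPHB3 at 7.72 ± 1.67 and 13.1 ± 0.753 TPM (adjusted p = 0.0697, and 0.0473 with a filter at 5 TPM). CTNNB1 was at 176 ± 6.04 and 160 ± 12.3 TPM (adjusted p = 0.350) and TCF7L2 at 30.6 ± 1.23 and 33.1 ± 2.92 TPM (adjusted p = 0.563). Chloride channels outside the CLIC family had 0 of 18 past the threshold (0 adjusted over the list alone; list adjusted p = 0.472), with CLNS1A at −0.13 (adjusted p = 0.134).

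Immune response genes were mixed. Antigen presentation genes had 2 of 16 higher, HLA-C (278 ± 4.46 to 314 ± 3.06 TPM), which has close relatives in sequence, among them, with 4 adjusted over the list alone (median 0.09, adjusted p = 0.00659, and adjusted p = 0.280 with an estimated correlation). That call was lost with GC, length and level trends removed, at a nearly unchanged median of 0.09 (adjusted p = 0.0712). Immediate early genes had 1 of 25 higher, IER2 (48.5 ± 1.18 to 61.2 ± 1.98 TPM), with 7 higher and 1 lower adjusted over the list alone (median 0.11, adjusted p = 0.00670, and adjusted p = 0.558 with an estimated correlation). That call was lost without knockdown replicate 1 (median 0.05, adjusted p = 0.0552). It was also lost once genes with TGCTGA in the 3′ UTR, and those with no searched 3′ UTR, were left out (median 0.09, adjusted p = 0.149). Without knockdown replicate 3 the median was 0.19 (adjusted p = 4.34e-04). Interferon-stimulated genes did not pass (1 higher adjusted over the list alone; adjusted p = 0.722), with OAS1 alone higher, 4.60 ± 0.307 to 7.16 ± 0.387 TPM. NF-kB and inflammatory genes had 0 of 14 past the threshold (0 adjusted over the list alone; list adjusted p = 0.739), with LCN2 at 776 ± 53.2 and 863 ± 21.5 TPM (adjusted p = 0.199). Cytosolic ribosomal protein genes had RPL23 and RPSA lower among 76 (5 lower and 1 higher adjusted over the list alone; median −0.03, adjusted p = 0.00194, and adjusted p = 0.558 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.256), median-ratio (0.0620) and trimmed-mean (0.0676) rescaling, without the variance trend (0.0762) and without knockdown replicate 1 (0.274, median −0.01), with no change of sign. The median was −0.01 after quantile normalization and −0.04 without knockdown replicate 3 (adjusted p = 9.55e-08). Replication-dependent histone genes had HIST1H1C higher (7.06 ± 0.307 to 11.3 ± 1.30 TPM) among 9 (4 adjusted over the list alone; median 0.38, adjusted p = 0.0179, and adjusted p = 0.375 with an estimated correlation). That call was lost without knockdown replicate 3 (median 0.41, adjusted p = 0.0775) and with no level filter (0.03, 0.277). Without knockdown replicate 1 the median was 0.23 (adjusted p = 0.0156).

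Markers of other cell types did not pass the test. Of the stromal, immune, endothelial and acinar or endocrine markers, 4, 1, 2 and 2 were tested and 0 passed over all genes. Adjusted over the list alone, 1 endothelial and 2 acinar markers were higher. The endothelial marker EGFL7 passed over all genes as higher in 1 of 20 other settings (limma adjusted p = 0.0442). The members with the smallest p in these lists were COL1A1 (1.8 ± 0.163 and 1.43 ± 0.509 TPM, adjusted p = 0.639), CD14 (4.87 ± 0.892 and 6.13 ± 0.488 TPM, adjusted p = 0.368), EGFL7 (30.7 ± 1.38 and 37.1 ± 0.795 TPM, adjusted p = 0.0760) and PRSS1 (3.15 ± 0.376 and 4.56 ± 0.480 TPM, adjusted p = 0.165).

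Of 302 KEGG pathways tested 13 passed, 8 higher and 5 lower, and of 2046 GO terms 48 passed, 22 higher and 26 lower. With an estimated correlation 0 of either passed, and the adjusted p of each of the 13 KEGG pathways was then 0.998. The lysosome pathway was higher (adjusted p = 0.0322), and in it 4 genes rose and 2 fell among 135. There the tetraspanin CD63 rose from 582 ± 11.9 to 700 ± 13.5 TPM and the protease CTSL from 45.5 ± 0.386 to 59.3 ± 1.90 TPM, while LAPTM4B, whose 3′ UTR carries GTGCTGA, fell from 38.5 ± 0.961 to 23.9 ± 1.74 TPM. Cell adhesion molecules were higher (adjusted p = 0.0222) in 3 of 62 genes, with the proteoglycan SDC1 rising from 49.2 ± 1.94 to 68.1 ± 4.28 TPM beside HLA-C. DNA replication was lower with 0 of 38 genes past the threshold (adjusted p = 0.0168).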

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

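The settings with genes listed at 0 left out, with GC, length and level trends removed and with TGCTGA genes left out were chosen only after the results were seen. CLIC1 kept its direction in all 20 settings and its side of the threshold in 19, with log2 fold changes from −0.58 to −0.52. limma without the trend ended that call at a log2 fold change of −0.54 (adjusted p = 0.0730). It also gave 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold, with 2040 genes at an unadjusted p under 0.05, 7 KEGG pathways and 31 GO terms. With no level filter 29306 genes were tested and 61 changed, 30 higher and 31 lower, 5 of them at least 2-fold, and 4 pathways passed. A filter at 5 TPM gave 12 genes changed at least 2-fold and 21 pathways. Library weights gave 392 genes, 228 higher, and 29 at least 2-fold. Replicate number as a term gave 41 genes, 21 higher and 20 lower, 7 at least 2-fold, 39 of them shared with the 246. Changes did not correlate best between samples of the same number, which shows no pairing by number but cannot exclude it. With GC, length and level trends removed, 493 genes changed, 246 higher and 247 lower, 219 shared with the 246, with 5 pathways and 28 GO terms, and RPL39P3 reversed (log2 fold change 0.0782). Leaving out TGCTGA genes, and those without a searched 3′ UTR, left 7043 genes, of which 12 changed at least 2-fold, with 20 pathways and 71 GO terms, and 70.1% of the calls were higher, against 55.3% of the 246. An estimated correlation gave 0 lists and fry 7. Without 1 library, counts ranged from 34 (without control replicate 2) to 242 (without knockdown replicate 3) genes changed, 13 to 154 higher, 19 to 88 lower and 6 to 27 at least 2-fold. Passing sets ranged from 17 to 21 lists, 7 to 12 pathways and 33 to 48 GO terms. These fits have fewer samples; for the other settings the cause was not tested. The cholesterol synthesis, G2/M and unfolded protein response lists passed in all 20 settings, though not with an estimated correlation. The same held for the glycolysis, S phase, p53, extracellular matrix, epithelial, classical and basal lists. Their highest camera adjusted p over the 20 settings lay between 0.00288 (basal) and 0.0131 (S phase). None of them passed fry, however (fry adjusted p from 0.0585 for basal to 0.201 for glycolysis). For glycolysis, a split of the libraries other than the real one gave a smaller camera p (9.52e-06 against 2.27e-05). TPM keeps no depth, so what depth limits cannot be given.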

Other observations

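The tests of whether the motif lies in CLIC1, of pairs of libraries, of sterol genes without a site, of single libraries in the subtype lists and of other splits, and the gene families named next, were chosen only after the results were seen. Keratins, the filament proteins of epithelia, had positive log2 fold changes in 11 of 11 tested genes, with KRT8, KRT18 and KRT19 past the threshold and a median of 0.32. S100 calcium-binding genes had 2 of 9 higher, S100A4 and S100A6 (1279 ± 31.7 to 1856 ± 176 TPM), with a median of 0.31. Secreted mucins and trefoil factors had 3 of 6 higher, TFF1, MUC6 and MUC5AC (median 0.88), while 0 of 3 transmembrane mucins passed (median −0.01). Medians kept their sign under the 4 other scalings in each of these families.

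Metallothioneins, which bind zinc and copper, had 2 of 6 lower, MT2A and MT1E (275.0 ± 5.61 to 199.3 ± 2.8 TPM), with a median of −0.23, chosen after its values were seen. Protein disulfide isomerases had 3 of 6 higher, PDIA4, P4HB and PDIA3 (392 ± 3.41 to 448 ± 8.9 TPM), chosen after its values were seen, with 6 of 6 positive. Cathepsins, proteases of the lysosome, had 2 of 11 higher, CTSL and CTSD (635 ± 2.32 to 766 ± 46 TPM), also chosen after its values were seen.

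Genes carrying GTGCTGA in the 3′ UTR were shifted down in knockdown, the lowest of 14917 sequences of 7 bases (1002 of 9238 genes, rank-sum z −13.4, with genes that are not independent replicates). It was also the lowest in a random 4619 of these genes (z −8.95), with a z of −9.94 in the other 4619, and spread within groups is argued against by the z of the motif between 2 libraries of the same group, at most 2.32 in size against −9.51 to −12.0 between a control and a knockdown library, though other sequences reached −6.25 within a group, and the motif was again the most extreme in the 9 other splits, which each keep part of the contrast (z −9.30 to 8.90). The median log2 fold change was −0.12 with the 8-base site GTGCTGAA, −0.06 with GTGCTGA alone, −0.05 with TGCTGAA, −0.01 with TGCTGA and 0.01 with none, and base composition is argued against by 350 sequences of the same bases, whose lowest z was −3.10. With called genes left out z was still −12.0, as a short RNA of seed TCAGCAC, such as the hairpin guide, would give. GTGCTGAA lies in 5 of 5 coding transcript models of CLIC1 (GRCh38 chromosome 6, 31732307 to 31732314, coding part of exon 6). These models belong to a single gene and count as a single observation. The sequence occurs in 4.73% of coding transcripts of similar length. The seed may therefore belong to a hairpin against CLIC1, but this match alone decides little. The hairpin sequence is not given in the sources used here, an endogenous RNA with the same seed was not tested, and which changes follow from the loss of CLIC1 stays open.

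The cholesterol synthesis list was lower in knockdown (adjusted p = 0.145 with an estimated correlation). A direct action of that short RNA on the 3′ UTR of each member is argued against by the 16 members with no TGCTGA there, whose median was −0.35, 7 of them lower. The standard error of that median, 0.0743, comes from resampling the 16 genes. They are not independent replicates, so it does not measure the spread between libraries. The 7 members with a site had a median of −0.43. The 3′ UTR of 1 transcript per gene was searched. Sites in coding sequences or other transcripts stay open. Library bias in GC, length or level is argued against by a median of −0.35 (−0.353991) after those trends were removed, and a single library by medians of −0.32 or lower without any 1 library. An indirect action, for example through HMGCS1, which carries the 8-base site, and an effect of CLIC1 loss may both account for it and stay open.

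Markers of both pancreatic cancer subtypes were higher as lists in knockdown (adjusted p = 0.392 for each list with an estimated correlation), with a median of 0.45 over 25 genes, 5 of which passed alone. Stromal, immune or endothelial cells in the knockdown cultures are argued against by 36 of 43 of their markers, which lay under 1 TPM in control and at most at 0.927 TPM in knockdown, 22 of them listed at 0 in all libraries (the ratio of summed TPM, 1.10, rests mostly on EGFL7 and ACTA2, the latter chosen after its values were seen, and decides little), and library bias by a median of 0.41 with GC, length and level trends removed. How far a single library sets the size stays open, as the lowest median without 1 library was 0.37 over both lists, but 0.14 for the classical list without knockdown replicate 2 and 0.21 for the basal list without knockdown replicate 1, with both lists still passing (adjusted p = 0.00755 and 9.79e-04). A seed of the control hairpin stays open too, since 0 of 24 searched members carry CGGAGAA, the 7 bases most enriched among higher genes, but only 0.512 would be expected at its frequency in all scanned genes, so the limit on this count set beforehand could not decide. An effect of CLIC1 loss, of the short RNA through other genes, or of clonal selection under puromycin may account for it, and none of these was tested.

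The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05, and the real split alone, 1 of 10, gave counts as large in each case. It gave 246 genes changed against at most 2 in the others, 136 higher against 1, 110 lower against 1 and 19 changed at least 2-fold against 2. It gave 20 lists against 12, 13 KEGG pathways against 5 and 48 GO terms against 18.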
